A study of Mus musculus with 12 samples.

How the data were processed

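Single-cell 3' RNA sequencing (10x Chromium, chemistry version 3) was deposited for 12 mouse samples from 3 sources of cells, with 4 samples each: tracheal allograft, native trachea and spleen. The labels call the cells of both trachea sources mesenchymal progenitors and those of the spleen splenocytes. They give no strain, sex, time after transplantation or treatment.

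The deposited values are raw counts of unique molecular identifiers (UMIs) per gene and barcode, made by the authors with Cell Ranger, version 3.1.0 per the file headers, on genome build mm10. The annotation release was not stated. There is 1 matrix per source, and all its barcodes carry the same suffix. Cells could therefore not be assigned to the 4 samples of a source, and each source was treated as 1 pooled library. The 3 matrices share a table of 31053 genes, of which 30934 identifiers were found in GENCODE release M21, the source of the positions given here. H2-Ea has no entry in that table under any symbol searched.

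Barcodes with 500 or more detected genes and 20% or less mitochondrial UMIs were kept, and doublets called per library with scrublet (in scanpy 1.11.5, expected rate 0.8% per 1000 barcodes) were removed. The caller marked 30, 40 and 20 of the barcodes of the allograft, native and spleen libraries, or 0.651%, 0.908% and 0.412%, while 3.69%, 3.70% and 3.88% were expected from the loading, so most doublets were left in. The 12540 cells used were clustered together (counts scaled to 10000 per cell and log-transformed, 2000 variable genes, 30 principal components, 15 neighbours, Leiden resolution 0.5) into 26 clusters with leidenalg 0.10.2 and igraph 0.11.9. Clusters were named from marker lists of 20 cell types. Of the 26 clusters, 6 did not meet the marker rule (3, 5, 10, 12, 19 and 24). Of these, 3, 5, 10 and 24 were placed in sets (neutrophil-marker, macrophage-marker, mesenchymal and phagocyte-marker) after their genes were seen. The markers, the gene lists, the rule for naming genes, the cell filter, the clustering settings and most alternatives were set before the data were examined. The sets of clusters that are compared were formed after the clusters were seen.

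For each comparison the UMIs of the cells were summed per library and expressed as counts scaled to the same total in each set (CPM). The ratio of CPM was computed with 0.5 UMI added to each sum, and its 95% interval is the exact conditional binomial one (scipy 1.17.1). Shares of cells carry exact Clopper-Pearson intervals, the limit beside a share of 0 is 3 cells of the total, and single CPM values exact Poisson intervals. All intervals cover counting error only. With 1 library per source, no difference was tested, no p-value is given, and spread between animals is unknown. A fold against 0 UMIs was computed against 3 counts and is given as a lower bound.

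Of 29 gene lists, those with 10 or more summed UMIs per member were described by the median log2 ratio, by the number of members 2-fold or more apart, and by the percentile of the median among 10000 random lists of the same size matched in 20 bins of expression. The genes named per comparison are the 12 highest and 12 lowest ratios among genes with 50 CPM or more and 30 UMIs or more in the higher library and a 2-fold difference or more. Mitochondrially encoded, ribosomal, immunoglobulin and T cell receptor genes and unnamed gene models were left out of that ranking. To them were added the 4 members with the largest ratios of each list described, cell type markers, Xist and Y-linked genes. Comparisons within clusters needed 50 or more cells in each library. For shares of cells with given transcripts, each cell was thinned to 1500 UMIs, which left out 350 allograft, 186 native and 141 spleen cells.

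The procedure was tested on simulated data, sums drawn from Poisson distributions with the proportions of the native library, in which 200 genes had known folds. For those genes the 95% intervals held the true ratio for 95% in the comparison of all cells and for 94% in that of cluster 3. The intervals assume counts of this kind, so that coverage was largely fixed in advance and checks the computation only. The simulation held no cells, so it says nothing of UMIs concentrated in few cells. The alternatives were other cell filters, doublets kept or removed by expected share, median-of-ratios scaling, per-cell scaling, totals without mitochondrial and ribosomal genes, thinning, Leiden resolutions of 0.3 and 1.0, separate clustering, and other minimums per list or set. The other tools were Python 3.11.15, numpy 2.4.6, pandas 2.3.3, anndata 0.12.19, scikit-learn 1.9.0 and matplotlib 3.10.9. No alignment was repeated, and barcodes that failed the filter entered only the alternative without a filter.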

Results

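The data comprised 3 pooled libraries of mouse cells, from a tracheal allograft, from native trachea and from spleen, each deposited for 4 samples. The series title asks about mononuclear phagocytes in the fibrosis of airways after transplantation. The libraries held 4611, 4626 and 4856 barcodes with 26503045, 31415458 and 28318436 UMIs in the order allograft, native and spleen. After the cell filter 3865, 4116 and 4559 cells remained, with medians of 4965, 6525 and 4421 UMIs per cell. There were no replicate libraries, so every difference below is one between 2 libraries, given with its counting interval.

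Most cells of both trachea libraries carried leukocyte markers, although their label names mesenchymal progenitors. Macrophage-marker clusters 1, 2 and 5 held 60.8% of the allograft cells (59.2 to 62.3) and 44.2% of the native cells (42.6 to 45.7), and 1783 and 1562 cells without cluster 5, which the marker rule left unnamed. Fibroblast cluster 7 and cluster 10, which mixed fibroblast and chondrocyte genes, together held 2.56% of the allograft cells (2.09 to 3.11) and 22.9% of the native cells (21.6 to 24.2). All 599 trachea cells of cluster 7 came from the native library. Natural killer (NK) cluster 13 had 175 allograft and 3 native cells, and T cell clusters 4, 6 and 11 held 10.9% (9.93 to 11.9) and 5.30% (4.63 to 6.03).

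In the spleen library 1942 of 4559 cells were in B cell cluster 0 and 25.0% (23.8 to 26.3) in the T cell clusters. Its phagocytes were mostly the 476 cells of cluster 8, led by Ace and Treml4, genes of non-classical monocytes. Cluster 1 was mostly allograft (1597 cells against 108) and cluster 2 mostly native (186 against 1454), and their leading genes differed between the libraries, so their sizes are not compared. Cluster 5, led by Mmp12, Gpnmb and Spp1, did not meet the marker rule and was placed with clusters 1 and 2 after its genes were seen. It held Csf1r, the receptor gene of macrophage growth factor, at 458 against 270.5 CPM (allograft against native), beside 27.04 against 48.7 CPM in T cell cluster 6. Clusters 15 and 20, with 125 and 49 spleen cells, stayed outside the phagocyte set although Cd5l and Ace were among their leading genes. How cells were isolated or sorted is not in the labels, and it sets these shares.

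**Figure D1:**
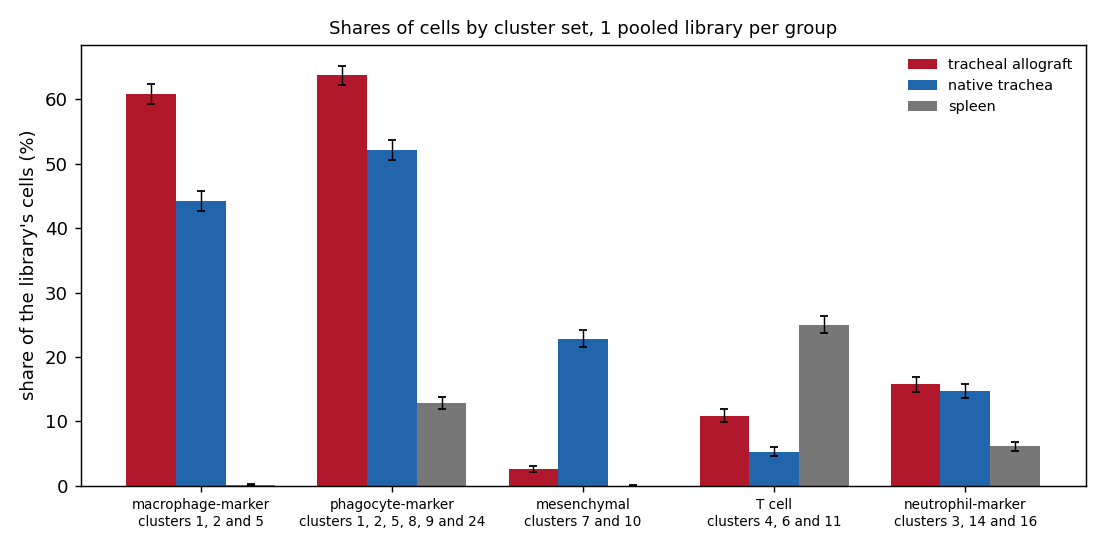
Share of the cells of each library (%, vertical axis) in 5 sets of clusters (horizontal axis) for the allograft, native and spleen libraries, with exact 95% intervals of counting error as bars. Macrophage-marker clusters held 60.8% of allograft and 44.2% of native cells, and mesenchymal clusters 2.56% and 22.9%.

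The comparison of the trachea libraries over all cells addresses how cells of a transplanted airway differed from those of an untransplanted one. Lists of interferon-induced genes, MHC class I presentation, cytotoxic lymphocytes and fibrosis-associated macrophage genes had higher medians in the allograft library, and those of collagens, other matrix genes and contractile genes lower ones. Cxcl9 (ENSMUSG00000029417, chromosome 5, 92321347 to 92328079), a chemokine induced by interferon gamma, stood at 348 against 13.05 CPM (26.6-fold higher, 24.1 to 29.5). Arg1 (ENSMUSG00000019987, chromosome 10, 24915221 to 24927484), the arginase of alternatively activated macrophages, stood at 69.04 against 0.956 CPM (72.2-fold higher, 50.1 to 108). Col1a1 (ENSMUSG00000001506, chromosome 11, 94936224 to 94953042), a chain of type I collagen, stood at 305 against 1159 CPM (3.81-fold lower, 3.71 to 3.90).

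The other highest ratios were those of Col2a1 and Acan, matrix genes of cartilage (44.5-fold, 37.6 to 53.01 and 22.1-fold, 17.9 to 27.6), of Ly6i (36.9-fold), Gbp4 (20.6-fold), Gbp2b (19.03-fold) and Il18bp (16.98-fold), of the chemokine Ccl8 (20.5-fold, 19.7 to 21.4), of the elastase gene Mmp12 (19.3-fold, 18.05 to 20.6), and of Nkg7 and Il2rb, genes of NK and activated T cells (22.03-fold and 18.3-fold). Ly6i, Gbp4 and Gbp2b belong to families of near-identical genes, so reads can be assigned to the wrong copy. Of 24 interferon-induced genes, 11 were 2-fold or more higher in the allograft library and 0 lower, with a median log2 ratio of 0.83, above the medians of all 10000 random lists. Igtp, an interferon-induced GTPase gene, was 6.76-fold (6.07 to 7.54) higher and Gbp2 5.70-fold (5.39 to 6.02).

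Genes of MHC class I presentation had a median log2 ratio of 1.19, and 10 of 12 were 2-fold or more higher. Among them were the immunoproteasome gene Psmb9 (4.23-fold, 4.003 to 4.47), the peptide transporter Tap1 (4.11-fold, 3.89 to 4.35), the transactivator Nlrc5 (3.64-fold, 3.23 to 4.12) and Psmb8 (2.87-fold, 2.78 to 2.96). MHC class II genes had a median of 0.50 with 1 of 10 past 2-fold, Ctss, which encodes cathepsin S (3.87-fold, 3.81 to 3.93). For cytotoxic and activated lymphocytes the median was 2.49, and 13 of 14 genes were 2-fold or more higher. Perforin (Prf1) was 38.7-fold (24.6 to 64.8) higher, Gzmb 26.01-fold (19.9 to 34.6), Ifng 26.2-fold (16.5 to 43.9) and Gzma 14.3-fold (12.8 to 16.04). The NK and T cell shares above differed in the same direction.

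Fibrosis-associated macrophage genes had a median of 1.04, and 9 of 17 measured members were 2-fold or more higher and 2 lower. Besides Arg1 and Mmp12, the secreted phosphoprotein gene Spp1 was 11.6-fold (11.1 to 12.1) higher, Gpnmb 8.36-fold (7.81 to 8.95) and Fabp5 6.76-fold (6.51 to 7.02), while Chil3 was 4.95-fold (4.62 to 5.32) lower. Phagocyte identity genes (0.85) and genes of lysosomes and phagocytosis (0.72) were higher as the macrophage share was. Hypoxia and glycolysis genes had a median of 0.94, with Bnip3 3.03-fold (2.62 to 3.52) and Pgk1 2.66-fold (2.55 to 2.77) higher and Adm 9.01-fold (6.56 to 12.7) lower.

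Matrix genes were lower in the allograft library, which held 99 mesenchymal cells against 941. Of 7 fibrillar collagen genes, 6 were 2-fold or more lower and Col11a1, a collagen of cartilage, was 10.9-fold (9.32 to 12.8) higher (median -1.88). Col1a2 was 4.13-fold (4.03 to 4.24) lower and Col5a1 5.74-fold (5.24 to 6.29). Among other collagens 9 of 11 genes were lower (median -3.55), and among matrix glycoproteins and proteoglycans 15 of 20 (-2.55), led by Mfap4 (83.1-fold, 69.6 to 100.04), elastin (Eln, 59.5-fold, 52.7 to 67.4) and Fbln1 (45.5-fold, 40.7 to 50.96). Contractile genes had a median of -2.90, with the smooth muscle genes Myl9 45.4-fold (32.7 to 65.1) and Acta2 9.998-fold (8.59 to 11.7) lower. Regulators of lung and airway mesenchyme stood at -3.05, collagen processing at -1.47, the TGF-beta pathway at -0.64 and progenitor surface markers at -0.42. In that last list Pdgfra was 24.2-fold (20.3 to 29.2) lower and Ly6a, which encodes Sca-1, 5.63-fold (5.41 to 5.86) higher.

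The lowest ratios were those of airway and lung epithelial genes and of mesenchymal genes of the native library. Sftpc, which encodes a surfactant protein of alveolar cells, had 0 and 11632 UMIs and was at least 3261-fold lower. Scgb1a1, the secretoglobin of club cells, was 726-fold (479 to 1159) lower and Bpifa1 4729.8-fold (1618 to 22938), with 22 and 3 UMIs in the allograft library. Scgb3a2, Scgb3a1 and Wfdc2, of the same epithelium, were 5596-fold (1004 to 221051), 869-fold and 896-fold (306 to 4349) lower, the first resting on 1 allograft UMI. Ces1d and Inmt were at least 1373-fold and at least 993-fold lower, Gria1 and Col13a1 at least 500.4-fold and at least 492-fold, and Fmo2 and Hhip 771-fold and 2132-fold (382 to 84235). The thyroglobulin gene Tg had 7672 native UMIs in 266 cells and the recombinase gene Rag1 135 in 55 cells, against 9 and 0 allograft UMIs.

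Dissociation and immediate early genes, which respond to tissue handling, were lower in the allograft library (median -1.002). Of 15 genes 8 were 2-fold or more lower, among them Jun (3.89-fold, 3.81 to 3.98), Egr1 (3.23-fold, 3.14 to 3.32) and Fos (3.22-fold, 3.16 to 3.29). Chemokines (-0.19), cytokines and growth factors (-0.39), complement (-0.51) and matrix proteases (-0.67) had members on both sides, such as Ccl5 (6.71-fold higher, 6.50 to 6.93), Il6 (19.2-fold lower, 16.3 to 22.8), Serping1 (17.01-fold lower, 16.01 to 18.1) and Mmp2 (15.8-fold lower, 14.8 to 17.001). No cell cycle gene of 20 and no unfolded protein response gene of 14 was 2-fold apart. The chondrogenic and osteogenic list stood at 1.26, with 8 of 14 genes higher and 4 lower. Senescence genes stood at 0.47, oxidative stress genes at 0.43 with Mt2 9.46-fold (9.01 to 9.94) lower, adipogenic genes at 0.33 and B cell differentiation genes at 0.20. Median-of-ratios scaling shifts all genes of this comparison by -0.03 on the log2 scale.

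Within macrophage-marker clusters 1, 2 and 5, the allograft library (2349 cells) had higher medians than the native library (1818 cells) for interferon-induced, MHC class I, fibrosis-associated and hypoxia genes. Nos2, the inducible nitric oxide synthase, stood at 58.6 against 0.0811 CPM, 723-fold (129 to 28586) higher with 1 native UMI. Arg1, which competes with it for arginine, was 116-fold (63.1 to 243) higher at 94.4 against 0.811 CPM. Gpnmb, a glycoprotein of lipid-laden macrophages, was 43.1-fold (35.5 to 52.8) higher, Spp1 26.8-fold (24.2 to 29.7) and Mmp12 12.2-fold (11.4 to 13.1).

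Also among the highest were Cxcl9 (40.6-fold, 33.9 to 49.2), Ccl8 (12.3-fold, 11.8 to 12.9, at 2098 against 170.2 CPM), Ly6a (62.3-fold, 51.9 to 75.3, at 596 against 9.57 CPM), Ly6i (99.9-fold), Il18bp (19.6-fold), Gbp4 (15.1-fold) and Fbxo32 (15.7-fold). In lymphocyte clusters 6 and 13 of the allograft and native libraries Gpnmb stood at 3.37 and 0.694 CPM, Ccl8 at 68.5 and 49.3 CPM and Arg1 at 4.87 and 5.55 CPM. These values hold free RNA and whatever lymphocytes express, and native Arg1 was higher in lymphocytes than in macrophage-marker cells. Ly6a, which spleen T cells hold at 331 CPM in cluster 4, has no such background in lymphocytes. The lowest ratios included Lyve1, a hyaluronan receptor (5.38 against 371 CPM, 69.03-fold lower, 56.5 to 85.2), and Cd163, the haemoglobin scavenger receptor (7.24 against 222 CPM, 30.7-fold lower, 25.8 to 36.9). Vsig4, a complement receptor, was 139.5-fold lower, Fcna 30.5-fold, Siglech 31.05-fold, Aqp1 60.5-fold and Tcim 249.9-fold. The lectin genes Cd209f, Cd209g and Cd209d, near-identical copies, were 61.03-fold, 68.4-fold and 25.2-fold lower. Bpifa1 (346-fold, 118 to 1684) and Scgb1a1 (52.8-fold), epithelial genes, were lower too, and native lymphocytes held 30.5 CPM of Scgb1a1, or 18.9 without 1 cell, and 12.5 CPM of Bpifa1, against 57.9 and 57.01 in native macrophage-marker cells. Arg1, Nos2, Cxcl9 and Ccl8 lead cluster 1, Gpnmb, Spp1 and Mmp12 lead cluster 5, and Lyve1, Cd163 and the Cd209 genes lead cluster 2, so over the 3 clusters these ratios also carry which library filled which cluster.

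**Figure D2:**
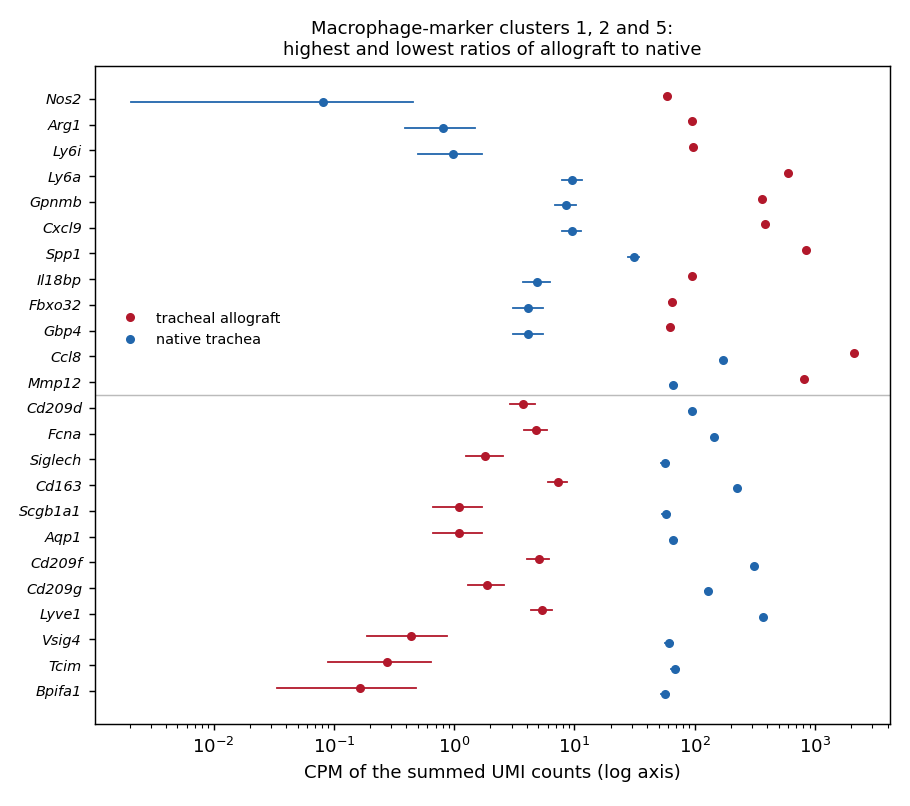
CPM of the summed UMIs (horizontal, log axis) in macrophage-marker clusters 1, 2 and 5 for the 12 highest and 12 lowest ratios of allograft to native (vertical axis). Points are the 2 libraries and lines exact 95% Poisson intervals of counting error, narrower than the point where not seen. Arg1 stood at 94.4 against 0.811 CPM and Lyve1 at 5.38 against 371 CPM.

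Interferon-induced genes had a median log2 ratio of 1.11 in these clusters, and 13 of 24 measured members were 2-fold or more higher and 1 lower. Iigp1 was 10.1-fold (8.14 to 12.7) higher and Gbp2 5.84-fold (5.38 to 6.35). MHC class I genes had a median of 1.05 (8 of 12 higher, 0 lower), with Tap1 3.79-fold (3.49 to 4.12) and Psmb9 3.63-fold (3.35 to 3.93). MHC class II genes had a median of 0.26, with H2-Ab1 at 9550.2 against 7939.99 CPM, and that median was -0.04 without a cell filter and -0.05 with the stricter filter or separate clustering. Fibrosis-associated macrophage genes had a median of 1.43 (9 of 17 higher, 2 lower). That value was 0.71 under the stricter cell filter and 0.89 in clusters 1 and 2 only, the latter chosen after the data were seen.

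Chemokines other than Cxcl9 and Ccl8 were mostly lower in the allograft macrophage-marker clusters (median -0.91, 4 of 20 higher and 10 lower). Ccl2, which recruits monocytes, was 4.44-fold (4.33 to 4.56) lower and Cxcl1, which recruits neutrophils, 3.99-fold (3.84 to 4.13). Cytokines and growth factors (median -0.57) included Il6 14.8-fold (10.99 to 20.2) lower and Vegfa 4.44-fold (4.06 to 4.87) higher. In the complement list (median -0.47, 2 of 14 higher and 5 lower) C3 was 4.11-fold (3.86 to 4.37) higher. Hypoxia and glycolysis genes had a median of 1.25 (8 of 13 higher, 1 lower), led by Egln3 (11.05-fold, 5.66 to 24.6) and Bnip3 (5.19-fold, 4.03 to 6.79). Lysosome genes had a median of 0.47, with Atp6v0d2 8.86-fold (7.26 to 10.9) and Ctsd 2.88-fold (2.82 to 2.95) higher. Immediate early genes stood at -0.97, with Hspa1a 3.63-fold (3.47 to 3.79) lower, alongside these lists.

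The direction was examined cluster by cluster because clusters 1 and 2 were filled by different libraries. Interferon-induced genes had medians of 1.43 in cluster 1, 1.14 in cluster 2 and 0.89 in dendritic cluster 9. In cluster 5 the median was 0.25 with 7 of 24 genes higher and 10 lower, and it was -0.07 under median-of-ratios scaling, which shifts all genes of that cluster by -0.32, -0.10 with thinned cells and -0.26 with a minimum of 50 UMIs. There Cxcl9 was 7.44-fold (5.38 to 10.6) higher and Cxcl10 8.79-fold (7.78 to 9.95) lower, as was Ifnb1 (44.3-fold lower, 24.9 to 86.98). Cluster 5 held the largest differences of Gpnmb (974 against 3.04 CPM), Spp1 (2239.9 against 31.95 CPM) and Trem2 (621 against 30.1 CPM) among the 3 clusters. With the libraries clustered separately, the counterpart of cluster 5 held 467 allograft and 12 native cells. Its native and allograft cells may thus be of different kinds, which these differences would also carry. In cluster 2 Ly6a was 55.97-fold (44.4 to 71.2) and Ccl8 11.5-fold (10.8 to 12.3) higher, and Cxcl13 stood at 1.49 against 130.4 CPM. In cluster 1 Arg1 had 1655 allograft and 0 native UMIs (at least 37.2-fold higher), and Chil3 was 14.3-fold (12.9 to 15.8) lower. MHC class I genes had positive medians in clusters 1, 2, 5 and 9 (1.04, 0.83, 0.65 and 0.97).

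**Figure D3:**
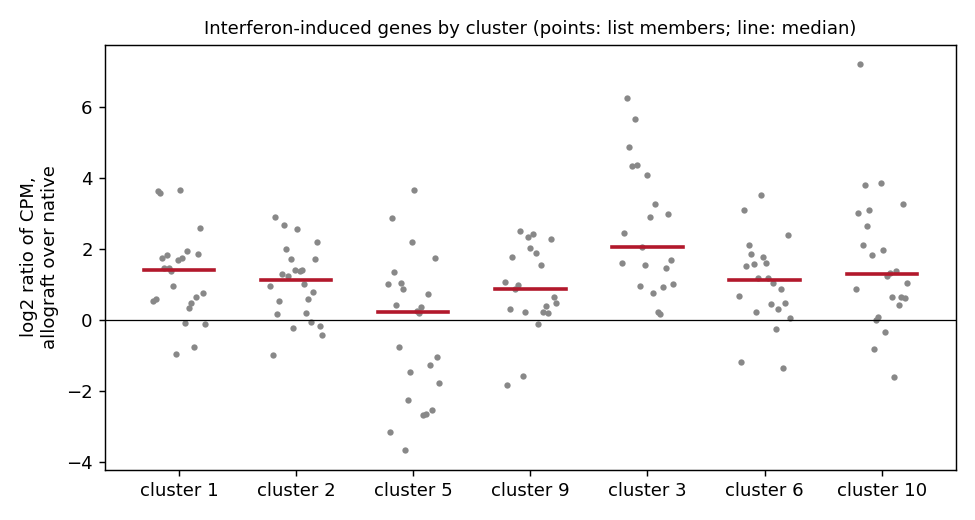
Log2 ratio of CPM, allograft over native (vertical axis), of each measured member of the interferon list (grey points) and their median (red line) in 7 clusters (horizontal axis). The median was highest in neutrophil-marker cluster 3 (2.05) and lowest in cluster 5 (0.25), where members lay on both sides of 0 and the sign depends on the scaling.

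Other leukocytes of the trachea showed the interferon difference too. In cluster 3, which carried neutrophil markers without meeting the naming rule (604 allograft and 573 native cells), the median of that list was 2.05, and 16 of 21 genes were higher and 0 lower. The guanylate-binding genes Gbp5 (222 against 3.92 CPM, 56.5-fold higher, 23.9 to 176) and Gbp2 (29.7-fold, 21.2 to 42.9) and the GTPase genes Ifi47 (21.6-fold, 11.8 to 43.99) and Igtp (17.5-fold, 10.4 to 31.7) led it. Retnlg was 4.28-fold (3.92 to 4.69) lower. MHC class I genes stood at 1.36. The median depth of these cells was 1714.5 and 1938 UMIs.

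T cell cluster 6 (410 allograft and 212 native cells) was higher in cytotoxic and activation genes in the allograft library, with a median of 2.40, 12 of 14 genes higher and 0 lower. Lag3, an inhibitory receptor, stood at 69.8 against 0.705 CPM, Gzmb was 21.2-fold (12.7 to 38.2) higher, Ifng 15.1-fold (8.67 to 28.7), and Foxp3, the regulatory T cell factor, 9.39-fold (5.22 to 18.6). Gzmc, Mmp13 and Gzme had 0 native UMIs (at least 76.1-fold, at least 61.6-fold and at least 25.6-fold higher). The native cells of the cluster included thymocyte-like cells: Dntt and Rag1 had 0 allograft UMIs and were at least 145-fold and at least 56.1-fold lower, and Ccr9 was 73.5-fold (33.4 to 202) lower. Cell cycle genes stood at -1.85, 16 of 20 lower. Without the sub-cluster led by thymocyte genes (7 allograft and 93 native cells), an alternative chosen after the data were seen, the cytotoxic median was 1.87. A native sub-cluster of 25 cells with 357 CPM of thymocyte genes, against 30.3 CPM in the largest sub-cluster, was still included there. Interferon-induced genes stood at 1.13 and MHC class I genes at 1.27 in the whole cluster. These medians and that of cell cycle genes include the 93 and 25 native cells of the sub-clusters with thymocyte genes. They thus also carry the mix of T cells and thymocyte-like cells in each library.

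Dendritic cluster 9 (83 and 271 cells) had Psmb9 4.56-fold (3.92 to 5.31), Ly6a 14.2-fold (9.95 to 20.9), the cytoskeletal gene Fscn1 7.93-fold (6.30 to 10.1) and the integrin gene Itgae 9.90-fold (6.44 to 15.7) higher in the allograft library. The metallothionein genes Mt1 and Mt2 were 9.20-fold (8.10 to 10.5) and 11.3-fold (8.18 to 16.1) lower. Cd163, a leading gene of macrophage-marker cluster 2, was 30.8-fold (10.4 to 150.5) lower. The leading genes of dendritic cluster 9 included Fscn1, Ccr7, Xcr1 and Cd209a, and the mix of dendritic cells in each library was not examined. With separate clustering the counterpart of cluster 9 held 91 allograft and 0 native cells. The median of all genes in this cluster was 0.35 and median-of-ratios scaling shifts it by -0.36, in cluster 3 by -0.13 and in cluster 2 by -0.12.

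The mesenchymal cells that could be compared were those of cluster 10 (99 allograft and 342 native cells). They were higher in the allograft library in genes of antigen presentation, interferon response and cartilage, and lower in contractile genes. MHC class II genes had a median of 2.83, and all 8 measured were 2-fold or more higher. The class II transactivator Ciita was 17.2-fold (8.23 to 41.6) higher and H2-Ab1 7.33-fold (6.81 to 7.88). Phagocyte genes were higher too, Lyz2 3.57-fold (3.29 to 3.88) and C1qa 2.45-fold (2.16 to 2.79), and at 1500 UMIs 15.3% of the allograft cells (8.83 to 23.99) and 4.75% of the native cells (2.74 to 7.60) held both phagocyte and mesenchymal genes. In the 35 allograft cells with a Y-linked UMI and no Xist, H2-Ab1 stood at 1226 CPM, in the 30 with Xist alone at 1074 and in the 23 with both at 5023, against 308 in the native cluster. MHC class I genes had a median of 1.52 and interferon-induced genes of 1.30, with Cxcl9 153-fold (98.8 to 251) higher.

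The chondrogenic and osteogenic list stood at 2.66, with Col2a1 85.4-fold (71.8 to 102), Acan 41.04-fold (33.2 to 51.2) and Spp1 56.8-fold (49.5 to 65.5) higher. Col10a1, the collagen of hypertrophic cartilage, had 764 and 0 UMIs (at least 557-fold higher), and H19, a growth-related RNA of fetal tissue, was 238-fold (129 to 499) higher. Fibrillar collagens stood at 0.94, with Col11a1 21.1-fold (17.9 to 24.9), Col1a1 2.09-fold (2.03 to 2.16) and Col3a1 1.91-fold (1.86 to 1.96) higher, and TGF-beta genes at 0.76, with Tgfb1 4.61-fold (3.89 to 5.47) higher and Ltbp1 6.24-fold (4.67 to 8.52) lower. Contractile genes stood at -1.48, with Acta2 7.39-fold (5.65 to 9.83) and Myl9 8.53-fold (5.87 to 12.9) lower. Such ratios also carry the mix of cells in the allograft cluster. Acta2 stood at 134 CPM in its 30 cells with Xist alone and at 1.09 in its 58 cells with a Y-linked UMI. Col1a1 stood at 16519 and 546 CPM in the same cells. Hhip, Ces1d, Cyp2e1 and Inmt had 0 allograft UMIs and were at least 169-fold, at least 127-fold, at least 126-fold and at least 106-fold lower.

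Cluster 10 of the allograft was also where Y-linked transcripts were found. Of its 99 cells 58 had a UMI of Ddx3y, Eif2s3y, Uty or Kdm5d (58.6%, 48.2 to 68.4, median depth 13426 UMIs), against 7 of the other 3766 allograft cells (0.186%, 0.0748 to 0.383, median 4843.5). At 1500 UMIs per cell the shares were 18.4% (11.3 to 27.5) and 0.117% (0.0319 to 0.299). In the native library 8 of 4116 cells had one (0.194%), and 0 of its 941 cells of clusters 7 and 10, which allows up to 0.319%. Xist, the RNA of the inactive X chromosome, was found in 75.7% of allograft, 82.8% of native and 87.1% of spleen cells. Within allograft cluster 10 the 58 cells with a Y-linked UMI held cartilage genes (Col2a1 5428 CPM, Acan 1782 CPM). Of these 58 cells 35 had no Xist (Col2a1 7389 CPM, Lyz2 170.03 CPM) and 23 also held Xist (401 CPM), with Col2a1 at 2778 CPM and the phagocyte gene Lyz2 at 2847 CPM, and 9 of the 23 held both phagocyte and mesenchymal genes. The 30 cells with Xist and no Y-linked UMI held fibroblast genes (Col1a1 16519 CPM, Col3a1 19773 CPM, and Postn, a matricellular protein of wound healing, 1675 CPM). Col1a1 was 30.2-fold (27.6 to 33.2) higher in those 30 cells than in the 58 cells, and Col2a1 25.2-fold (20.4 to 31.4) higher in the 58. The list medians of this cluster thus combine several kinds of cell.

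**Figure D4:**
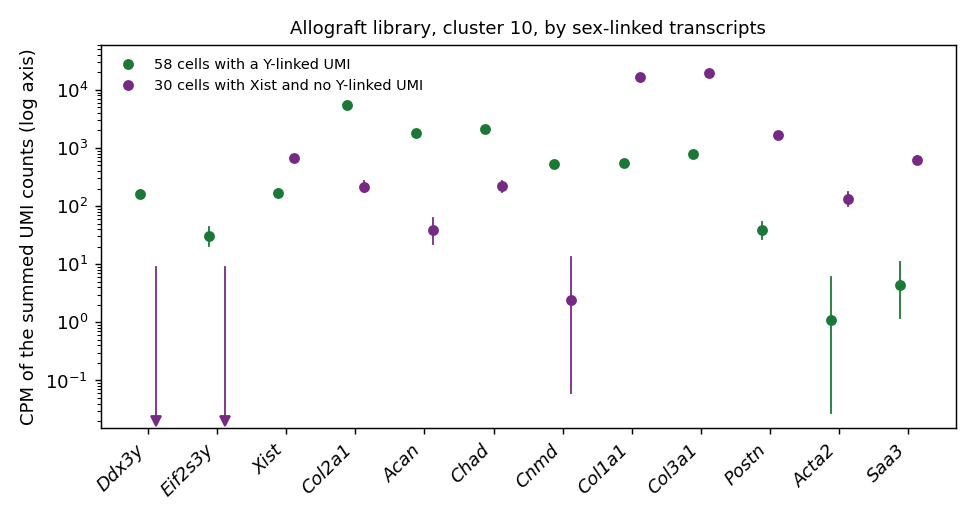
CPM of the summed UMIs (vertical, log axis) of 12 genes (horizontal axis) in allograft cluster 10, for the 58 cells with a Y-linked UMI and the 30 cells with Xist and none, with exact 95% Poisson intervals of counting error. Arrows mark 0 UMIs and their upper limit. Col2a1 stood at 5428 and 216 CPM, and Col1a1 at 546 and 16519 CPM.

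The comparison of phagocytes with those of the spleen relates the cells of the graft to phagocytes outside it. The 2462 allograft cells lay mostly in clusters 1, 5 and 2, and the 584 spleen cells mostly in cluster 8. Only 7 of those spleen cells lay in macrophage-marker clusters 1, 2 and 5, and 22 held C1qa. Spleen cluster 15, with Cd5l among its leading genes, was outside the set. The phagocyte ratios to the spleen below thus also carry which kinds of phagocyte each library held. The allograft cells had higher levels of chemokines, matrix proteases, complement and fibrosis-associated genes. Gpnmb had 6634 and 0 UMIs (at least 302-fold higher), Spp1 15251 and 1 (2085-fold higher, 374 to 82355), and Ccl8 stood at 1979 against 3.40 CPM (582-fold higher, 307 to 1273). Fibrosis-associated genes had a median of 3.97 (13 of 17 higher, 1 lower), with Arg1 at least 78.5-fold, Retnla 73.1-fold (55.8 to 97.6) and the mannose receptor gene Mrc1 68.4-fold (43.3 to 115) higher.

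Of 20 chemokine genes 18 were higher (median 3.30, 3.06 with genes at 0 set to their bound), among them Cxcl1 (at least 184-fold), Ccl12 (at least 126-fold) and Cxcl2 (158-fold, 116 to 222). Of 15 matrix protease genes 14 were higher (median 4.42, 3.26 with genes at 0 set to their bound), such as Mmp19 (154-fold, 78.3 to 358) and Ctsk, the collagen-degrading cathepsin K (114-fold, 31.5 to 943). Complement stood at 2.32, with C1qa 51.5-fold (44.2 to 60.4) higher, and MHC class II at 1.89, with H2-Ab1 4.67-fold (4.54 to 4.79) higher. Interferon-induced genes stood at 0.67 and phagocyte identity genes at -0.07. Higher in the spleen were Ace (79.7-fold, 66.3 to 96.5), Treml4 (42.3-fold, 36.2 to 49.8), the egress receptor S1pr5 (482-fold, 219 to 1320.2) and Pglyrp1 (95.2-fold, 74.2 to 124), of which Ace, Treml4 and S1pr5 lead cluster 8, where most of its phagocytes lie. Median-of-ratios scaling shifts all genes by 0.46 here and by 0.59 in the native comparison, and the phagocyte identity median becomes 0.39.

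Native trachea phagocytes (2143 cells, mostly clusters 2, 9 and 5) differed from those of the spleen in the same direction for chemokines (3.72, 3.24 with genes at 0 set to their bound), complement (3.54, 3.29 with genes at 0 set to their bound) and fibrosis-associated genes (1.99). For interferon-induced genes the sign was the opposite, with a median of -0.72, 4 of 24 genes higher and 11 lower than in the spleen, but the median was -0.13 under median-of-ratios scaling, with 4 higher and 3 lower, and -0.21 with thinned cells. Cxcl1 was at least 630.4-fold higher, Retnla 234-fold (179 to 312) and Fcrls at least 406-fold. Ly6i (107-fold, 68.4 to 178) and S1pr5 (254-fold, 133 to 561) were lower.

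Over all cells, both trachea libraries had higher medians of chemokines and lower ones of B cell and cell cycle genes than the spleen. Chemokines stood at 5.996 (5.69 with genes at 0 set to their bound) for the allograft and 5.87 for the native library, with Ccl7 at 508, 899 and 0.0720 CPM in allograft, native and spleen. Fibrillar collagens were near 0 in the spleen, where Col1a1 had 2 UMIs. B cell differentiation genes stood at -5.53 and -6.31, with the complement receptor gene Cr2 1745-fold (681 to 6405) and 395-fold (258 to 639) lower, and cell cycle genes at -2.42 and -2.45. The haemoglobin genes Hbb-bs and Hbb-bt were 6240.1-fold and 5601-fold (1550.1 to 46251) lower in the allograft library. Interferon-induced genes stood at 1.32 and 0.22, and MHC class I genes at 0.56 and -0.64, negative in the native library with Psmb9 5.21-fold (4.94 to 5.50) lower. Ribosomal UMIs made up 12.5%, 12.7% and 26.7% of the allograft, native and spleen libraries. Totals without mitochondrial and ribosomal genes shift these comparisons by -0.29 and median-of-ratios scaling by 0.18 and 0.16, and the native interferon median is -0.07 under the first and -0.16 as the mean of per-cell CPM.

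NK cluster 13 could be compared between allograft (175 cells) and spleen (77 cells). Pmepa1, a target of TGF-beta signalling, stood at 708 against 3.36 CPM (211-fold higher, 37.7 to 8339.7, 1 spleen UMI) and Vegfa was 53.6-fold (14.7 to 445) higher in the allograft library. The NK receptor gene Ncr1 was 15.3-fold (11.6 to 20.4) lower, Cd160 16.6-fold (9.70 to 30.1), Klrg1 8.44-fold (4.88 to 15.3) and S1pr5 23.5-fold (10.1 to 66.9). Cytotoxic and activated lymphocyte genes stood at -0.23 and interferon-induced genes at 0.07. Granzyme A (Gzma) stood at 4619.7 against 9369 CPM.

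Cells with transcripts of both phagocytes and mesenchymal cells bear on the question in the title. At 1500 UMIs per cell, 35 of 3515 allograft cells (0.996%, 0.695 to 1.38) and 50 of 3930 native cells (1.27%, 0.946 to 1.67) had 2 or more of 6 phagocyte genes and 2 or more of 6 mesenchymal genes. The phagocyte set, which includes Ptprc, Tyrobp and Fcer1g, is not specific: 44.8% of allograft lymphocytes (40.7 to 49.05) and 99.8% of allograft cluster 3 cells held 2 or more of it. In the spleen 0 of 4418 cells held 2 or more genes of both sets, which allows up to 0.0679%. Without thinning the shares were 5.07% and 8.38%. The intervals of the trachea libraries overlap. With the expected share of doublets removed, an alternative chosen after the data were seen, the shares were 0.883% and 0.838%, so their order turns. The median doublet score was 0.0543 in the 35 allograft cells against 0.0335 in the others, and 0.0439 in the 50 native cells against 0.0246. Of the 35 allograft cells 19 lay in the macrophage-marker clusters and 15 in cluster 10, and of the 50 native cells 12 and 16.

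In the allograft macrophage-marker clusters Col1a1 stood at 11.6 CPM (10.1 to 13.3), Col3a1 at 13.7 (12.1 to 15.5) and Dcn at 12.3 (10.7 to 14.01). In lymphocyte clusters 6 and 13 of that library they stood at 2.62 (1.05 to 5.40), 7.86 (4.87 to 12.02) and 29.9 CPM, and the last is 4.16 without the 1 cell that held 69 of its 80 UMIs. In native macrophage-marker cells Col1a1 stood at 14.6 CPM (12.5 to 16.9), Col3a1 at 19.7 and Dcn at 34.5 (31.3 to 37.99). Native lymphocytes had 47.9, 52.7 and 176 CPM of them, and 14.3, 17.9 and 20.8 CPM without the 1 cell richest in each gene. Without that cell the order turns for each of these genes, for Col1a1 by little. The mesenchymal clusters held 5300.01 CPM of Col1a1 in the allograft and 3404 in the native library.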

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

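The tests of the Y-linked transcripts below were chosen after the result was seen. Barcodes with more than 20% mitochondrial UMIs made up 12.2% of the allograft barcodes (11.2 to 13.1), 8.60% of the native barcodes (7.81 to 9.45) and 3.77% of the spleen barcodes (3.25 to 4.34). They stand out because the cell filter removes them and the comparisons include them only in the alternative without a filter. The difference between the libraries was not tested, and with 1 library per source it cannot be separated from handling.

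Y-linked transcripts were found in 58 of 99 cells of allograft cluster 10 and in few cells elsewhere, and the labels state no sex. Free RNA from male cells would spread over the library, but at 1500 UMIs per cell 0.117% of the other allograft cells held a Y-linked UMI (0.0319 to 0.299). Depth was also excluded as the cause, since at that equal depth the share in cluster 10 was 18.4% (11.3 to 27.5). Xist was lower in the cells with a Y-linked UMI, 0.301 of the level in the other cells of the cluster (0.246 to 0.366), but not absent: 35 of the 58 cells held none and 23 held both, at 401 CPM of Xist, 9 of those with phagocyte genes as well, so part of them may be doublets or hold free RNA. The values suggest, as a hypothesis, that the 35 cells came from a male animal and other cells from females, which the sex of donors and recipients would settle.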

How the results depend on the processing

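Of 139 values of 15 leading results under the alternatives, 97 stayed within the limits set for them, 42 moved and 0 reversed. The other minimums per list left nearly all of the leading list medians unchanged, and those values count among the 97. By the rule used, shares of cells could only stay or move. List medians near 0 that changed sign were not counted as reversed. The absence of reversals was thus partly set by the rule. Of 950 values of 87 list medians 261 moved, and of 2064 values of 192 named genes 152 moved and 2 reversed. For those that moved or reversed the cause was not tested. Leaving out a library was impossible with 1 per source. Removing the expected share of doublets, clusters 1 and 2 only, and leaving out the thymocyte sub-cluster were alternatives chosen after seeing the data.

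Over all cells, allograft against native, the fibrillar collagen median was -2.27 as the mean of per-cell CPM and -2.22 with thinned cells, and the interferon median 1.07 and 1.09. The chemokine median against the spleen was 4.86 for the allograft as the mean of per-cell CPM and 5.70 without mitochondrial and ribosomal genes. For the native library it was 5.33 and 5.58 under these settings and 6.03 under median-of-ratios scaling.

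In the macrophage-marker clusters the median of fibrosis-associated genes was 1.26 without a cell filter, 0.71 with the stricter filter, 1.35 with doublets kept, 1.29 as the mean of per-cell CPM, 1.26 with thinned cells, 1.31 at Leiden resolution 0.3, 1.21 with separate clustering and 0.89 in clusters 1 and 2 only. The interferon median was 1.41 in clusters 1 and 2 only. For phagocytes of the allograft against the spleen the fibrosis-associated median was 4.43 under median-of-ratios scaling, 3.65 as the mean of per-cell CPM and 4.22 with thinned cells. Adam23, lower in the allograft phagocytes, had a log2 ratio of 0.44 at Leiden resolution 1.0, and Hspa1b of cluster 3 one of -1.49 with the stricter filter.

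In cluster 6 the cytotoxic median was 1.96 with thinned cells, 2.003 at Leiden resolution 0.3 and 1.87 without the thymocyte sub-cluster. In cluster 10 the MHC class II median was 2.40 with doublets kept, 3.27 as the mean of per-cell CPM, 3.28 with thinned cells and 3.47 with the expected share of doublets removed. No value was had where a cluster had no counterpart: cluster 9 without a filter, with the stricter filter and at Leiden resolution 0.3, and clusters 5 and 10 at Leiden resolution 0.3. The counterparts had under 50 cells in a library for cluster 6 without a filter (19 allograft cells), cluster 10 without a filter (20 native cells), and clusters 5 and 9 with separate clustering (12 and 0 native cells).

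The share of phagocyte-marker cells was 67.1% in the allograft library without a filter and 74.2% with the stricter one, and in the native library 55.2%, 59.0% and, at Leiden resolution 0.3, 53.7%. The native mesenchymal share was 20.7% without a filter and 27.9% with the stricter one. Cells with both sets made up 0.256% of the allograft library with 3 or more genes of each set, 6.97% with 1 or more and 5.07% unthinned, and 0.356%, 12.4% and 8.38% of the native library, which had 0.838% with the expected share of doublets removed. Depth limits these shares, as the unthinned values show.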

Other observations

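The free RNA tests with 2 or more genes, the native doublet test and the interferon test below were set before their values were seen, and the other tests were chosen after. Cells with cartilage genes in the graft, summed together, held transcripts of MHC class II, which is usual for phagocytes and B cells. In the 35 cells of allograft cluster 10 with a Y-linked UMI and no Xist, Cd74 stood at 3573 CPM, 14.5% of the level in the allograft macrophage-marker cells, and H2-Ab1 at 12.8% of it. The macrophage genes Lyz2, Tyrobp, C1qa and Apoe stood at 2.32%, 5.49%, 6.22% and 7.67% of that level in the same cells. Ciita, the regulator of the class II genes, stood at 28.3 CPM (15.9 to 46.7), 40.3% of the macrophage level, on 15 UMIs. How many of the 35 cells held class II UMIs was not counted. The genes set beside class II are those of macrophages, so RNA from dendritic or B cells was not examined. In native cluster 10 Cd74 stood at 4.196%, Lyz2, Tyrobp and C1qa at 4.42%, 4.13% and 3.11%, and Apoe at 15.5%, so Apoe does not separate the libraries in this way.

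The native library held several genes of neighbouring organs. Tg, of the thyroid, had 7672 UMIs in 266 cells, Sftpc, of lung alveoli, 11632 in 89 cells, Rag1, of the thymus, 135 in 55 cells and Dntt 343 in 46 cells. The allograft library had 9, 0, 0 and 5 UMIs of these genes. Marco and Ccr9, also looked at for lung and thymus, were not specific to the native library, with 224 and 130 allograft against 300 and 404 native UMIs.

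Mesenchymal transcripts in the allograft macrophage-marker cells exceeded the background of that library in 1 of 2 tests of free RNA. With 2 or more genes at 1500 UMIs the share was 0.855% (0.516 to 1.33) against 0.179% of lymphocytes (0.00452 to 0.991), intervals that overlap. With 1 or more gene it was 7.52% (6.46 to 8.70) against 2.5% of lymphocytes (1.37 to 4.16) and 3.61% of neutrophil-marker cells (2.03 to 5.88). Doublets stay open for the 19 cells with 2 or more genes, whose median doublet score was 0.0413 (0.0227 to 0.0666) against 0.0396 in the others and whose median level was 5.55% of the mesenchymal one (2.62 to 9.09), 4 of them at 10% or more. A test by level, chosen after the score did not decide, gave 0.824% (0.736 to 0.880) in the 561 cells with a UMI of the set, too little for doublets in most of them, though with a median of 1 UMI that value is near the lowest possible; uptake of RNA or low expression may account for them and was not tested.

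In the native library the same transcripts could be free RNA. The share of macrophage-marker cells with 2 or more genes was 0.740% (0.395 to 1.26) against 1.44% of lymphocytes (0.297 to 4.14), and with 1 or more gene 14.6% (12.96 to 16.3) against 9.57% (5.94 to 14.4). The 14.6% lay just above the upper limit of lymphocytes, with overlapping intervals, and within that of neutrophil-marker cells. Before thinning, lymphocytes numbered 215 in the native and 585 in the allograft library, so the native lymphocyte intervals are wider. The 13 macrophage-marker cells with 2 or more genes had a median doublet score of 0.0228 (0.0203 to 0.0381), below the 0.0287 of the other macrophage-marker cells. The interval holds that value, so the score does not exclude doublets. Their median level was 2.90% of the mesenchymal one (2.05 to 5.55), with 2 of them at 10% or more.

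Ly6a was low in native macrophage-marker cells, and the present level of other interferon-induced transcripts did not account for this in cluster 2. There the 93 allograft cells with few UMIs of other interferon-induced genes had 9.95 times the Ly6a (6.66 to 15.3) of the 145 native cells with the most, at 0.591 of their level of those other genes (0.529 to 0.658). Past exposure and the kind of interferon were not measured, so interferon itself is not excluded as the cause. Assignment of Ly6a reads to other Ly6 genes did not account for the difference, since the sum of these genes, Ly6a included, was 20.1 times higher (18.4 to 22.1), 813 against 40.4 CPM. Shared reads that were left uncounted would be missing from that sum too, so the sum cannot exclude them. Native cluster 10, endothelial and epithelial cells held 531, 518 and 482 CPM of Ly6a and native fibroblast cluster 7 held 83.6. Cluster 19, unnamed and led by genes such as Ccr7 and Cxcr5, held 645 CPM in the native and 299.98 in the allograft library. It was an exception among the native leukocyte clusters examined for Ly6a, which were not all of them. T cell cluster 6, its thymocyte-like native cells included, held 51.5 against 436 CPM (native against allograft). Cluster 3 held 6.28 against 54.7 and dendritic cluster 9 held 14.2 against 202. Strain is not in the labels, and its part was not tested.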
